A study of Rattus norvegicus with 12 samples.

How the data were processed

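RNA from the prefrontal cortex of 12 rat offspring in early adolescence was sequenced, 1 library per animal, 4 animals in each of 3 groups. The groups were saline controls, offspring with postnatal oxycodone exposure (PNO) and offspring with in utero oxycodone exposure (IUO). The labels give poly(A) stranded libraries, oxycodone at 15 mg/kg by mouth and dosing that ran to postnatal day 21 at the latest, without saying which window belongs to which group. Each group came from 2 dams with 2 animals per dam. The labels do not tie an animal to a dam, so dam was not a term in any model and p values over animals may be too small.

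The authors named HISAT2 for alignment and StringTie for quantification. Their versions and settings, the genome build and the annotation release are not given in the sources used here. The deposited table holds 22431 genes with Ensembl rat identifiers, and each has whole-number counts per library. The deposited table also holds FPKM (fragments scaled to gene length and library size), as named in the file headers. Gene positions are those printed in the deposited table. Total counts ran from 49227533 to 60672246 per library, so counting error was small beside the spread between animals for all but genes with few counts.

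The test written before the data were examined was limma on log2(FPKM + 0.5), on the assumption that the table held FPKM alone. Because the table also held counts, the main test became the edgeR quasi-likelihood test on counts, with the planned filter, samples, adjustment and threshold kept, and the limma test was run as an alternative. Genes with a mean FPKM of at least 0.5 over the 12 libraries were kept, which left 14170 genes. Libraries were scaled with TMM factors and 1 model with the 3 groups was fitted to all 12 libraries. Tests were two-sided, p values were adjusted by Benjamini-Hochberg within each comparison and the threshold was an adjusted p under 0.05. Levels are CPM (counts scaled to library size) given as mean ± SD, and log2 fold changes are edgeR's with their standard error (SE). Log2 CPM per library used a prior count of 2. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

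Of 29 gene lists fixed before the data were examined, 28 were tested with camera, a competitive test of a list against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. The same test was run with a correlation estimated from the residuals. The lists covered opioid receptors and peptides, immediate early genes, myelin and mature oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, inflammation, interferon response, GABAergic neurons and GABA-A receptor subunits. They also covered glutamate receptors and transporters, monoamine receptors, presynaptic vesicle machinery, postsynaptic density, cortical layer markers, glucocorticoid response and stress axis, heat shock and unfolded protein response, circadian clock, cytosolic ribosomal proteins, and nuclear-encoded respiratory chain subunits. The rest were mitochondrially encoded genes, histone genes, endothelium and pericytes, and markers of meninges, choroid plexus and ependyma, blood, striatum and olfactory bulb. The sex-linked list was read per library and not tested. Some members stand on more than 1 list. Among them, Penk and Pdyn are striatal and opioid genes, Drd1 and Drd2 are striatal and monoamine receptor genes, and Per1 is a clock and an immediate early gene.

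Named genes followed a rule fixed before the data were examined. In each comparison it took the genes past the threshold, and, where fewer than 10 passed, the genes with the smallest unadjusted p up to 10. It added up to 4 members with the smallest unadjusted p of each list that passed, members that passed over their list alone, and 5 opioid genes (Oprm1, Oprd1, Oprk1, Penk and Pdyn). The PNO and IUO effects were compared by Pearson's r across genes, beside 100 simulations of unchanged groups with the same shared controls and beside splits of the 4 controls into 2 and 2.

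Alternatives planned before the data were examined were other pseudocounts (0.1 and 1), no filter, a mean FPKM of at least 2, FPKM on the TPM scale, median-of-ratios size factors, a fit of only the 2 groups compared, robust estimation, sample weights (limma's voomWithQualityWeights in place of its array weights), the replicate number as a block, an estimated correlation for the lists, and leaving out each library in turn. A planned covariate of the Xist level was not run, because the table holds no Xist. The planned limma test became an alternative after the data were seen. Alternatives added then were DESeq2, DESeq2 with striatal and bulb scores as covariates, a Y-linked covariate, striatal and bulb scores as covariates without and with the Y-linked level, leaving out the 4 libraries with raised striatal markers, leaving out the 4 with raised bulb markers, and removal of a trend on gene length in each library. Leaving out the striatal-marker libraries kept 3 control, 3 PNO and 2 IUO libraries, and leaving out the bulb-marker libraries kept 4 control, 1 PNO (PNO 2) and 3 IUO libraries. A library counted as raised when its score stood more than 0.5 above the lowest control library. The bulb score used as a covariate and for this choice left out Npy, which also stands on the GABAergic list, so it differs slightly from the list means printed in the results.

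The tests were checked on simulated data in which known changes were planted in counts with the spread of the real libraries. For PNO against control edgeR recovered 41.8% of 67 genes changed 1.5-fold, 77.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 6 false calls among 149. DESeq2 recovered 67.2%, 85.1% and 97.0%, with 30 false calls among 198, and limma 38.8%, 76.1% and 95.5%, with 7 among 147. Camera called the shifted list and 0 of 10 unshifted lists. The simulated genes were drawn independently of each other, so this check does not cover lists whose members vary together. The estimated correlation of the respiratory chain list, for example, was 0.587 in PNO against control. No genome sequence was used, so GC content was not checked. Results for 6 genes are not reported here.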

Results

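Poly(A) RNA of the prefrontal cortex was sequenced in 12 rat offspring in early adolescence, 4 saline controls, 4 with postnatal oxycodone exposure (PNO) and 4 with in utero oxycodone exposure (IUO). Oxycodone is an opioid agonist, given at 15 mg/kg by oral gavage. Total counts ran from 49227533 in IUO 2 to 60672246 in control 1, and mitochondrially encoded genes took 15.1% to 18.9% of counts. Pearson's r of log2 CPM between libraries of a group, taken across the 14170 tested genes, lay between 0.954 and 0.983. The Y-linked gene Eif2s3y exceeded 10 CPM in 2 of 4 control, 2 of 4 PNO and 1 of 4 IUO libraries, and the labels do not give the sex of the animals.

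Markers of regions that border the dissected cortex differed between libraries of the same group. The mean log2 CPM of 13 striatal genes, among them the dopamine receptor gene Drd2 and the phosphodiesterase gene Pde10a, was 6.34 in PNO 2, 5.84 in IUO 2, 4.81 in IUO 1 and 4.68 in control 2. It lay between 3.63 and 3.82 in the other 8 libraries. The mean of 9 olfactory bulb genes, among them the mitral and tufted cell genes Eomes, Tbx21 and Cdhr1, was 4.51 in PNO 1, 4.37 in PNO 3, 4.64 in PNO 4 and 5.06 in IUO 3. It lay between 2.37 and 2.87 in the other 8 libraries, and all 4 control libraries were among those. Markers of meninges, choroid plexus and blood also varied within groups: the mean log2 CPM of 14 meningeal genes ran from 4.18 in IUO 2 to 5.10 in PNO 3, that of 6 choroid plexus genes from 0.74 in IUO 3 to 2.99 in IUO 2, and that of 8 blood genes from 1.75 in control 4 to 4.19 in IUO 4.

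**Figure D1:**
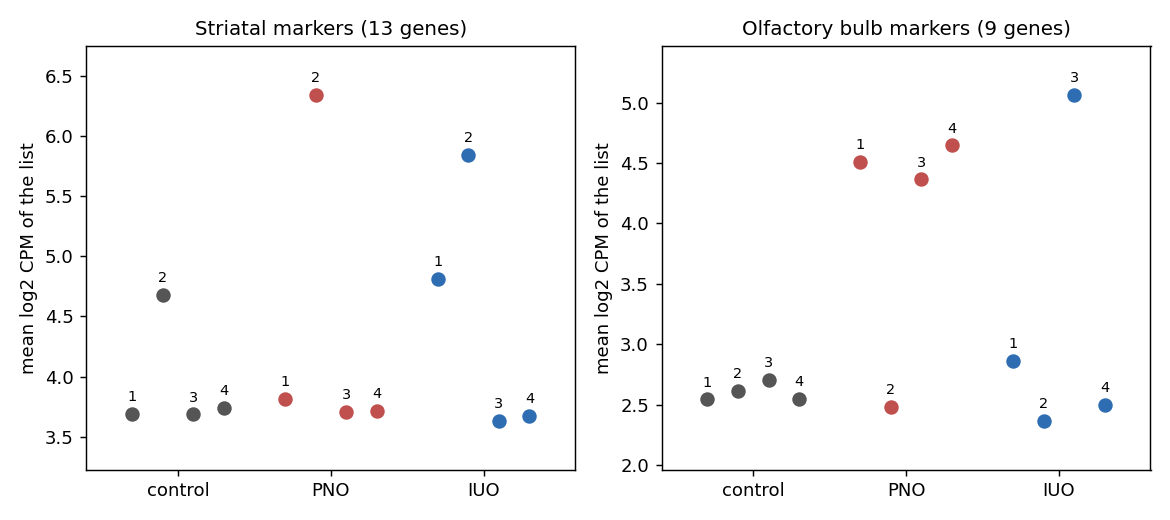
Mean log2 CPM of 13 striatal genes and of 9 olfactory bulb genes in each of the 12 libraries, with the replicate number beside each point. PNO 2 has the highest striatal mean (6.34) and IUO 3 the highest bulb mean (5.06).

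The comparison of PNO with control asked what the exposure labelled postnatal left in the prefrontal cortex at early adolescence. The lists of GABAergic neuron genes and of glutamate receptors and transporters were higher in PNO (adjusted p = 0.00249 and 5.44e-04, and adjusted p = 0.407 for each with an estimated correlation). Gad1, which encodes a GABA-synthesising enzyme, measured 267 ± 32.2 CPM in PNO and 182 ± 15.5 CPM in control (SD, n = 4 each), a log2 fold change of 0.55 (SE 0.12). Gria1, an AMPA receptor subunit, measured 86.0 ± 14.9 CPM against 53.8 ± 6.68 CPM, and Unc13a, which primes synaptic vesicles, 161 ± 23.0 CPM against 104 ± 12.4 CPM. Each of these genes was higher in all 4 PNO libraries than in all 4 control libraries. The list of nuclear-encoded respiratory chain subunits was lower, with a negative log2 fold change in 73 of 75 members and a median of -0.20 (adjusted p = 1.50e-12, and adjusted p = 0.476 with an estimated correlation). No gene passed over all 14170 tested: edgeR called 0 genes, with a smallest adjusted p of 0.305 and 1564 genes (966 higher, 598 lower) at an unadjusted p under 0.05 where chance gives 708. DESeq2 called 117 genes (94 higher, 23 lower), among them Gad1, Gria1 and Unc13a, limma on log2(FPKM + 0.5) called 1, limma with sample weights 32, and edgeR on the 8 libraries of this comparison alone 11. DESeq2 with striatal and bulb scores as covariates called 9 genes (7 higher, 2 lower), and Gad1, Gria1 and Unc13a were not among them.

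Of the 14 GABAergic neuron genes, 10 had a positive and 4 a negative log2 fold change in PNO, with a median of 0.48. The list was higher by the camera test (adjusted p = 0.00249, and adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone 2 members passed, Gad1 (adjusted p = 0.00703) and Dlx5 (adjusted p = 0.0268), against 0 over all genes. Dlx5, a transcription factor of GABAergic neurons, measured 13.1 ± 1.26 CPM in PNO and 5.67 ± 2.07 CPM in control, and the vesicular GABA transporter gene Slc32a1 measured 115 ± 20.3 CPM and 72.0 ± 20.8 CPM. Sst, the somatostatin gene, had the opposite sign at 173 ± 17.0 CPM in PNO and 218 ± 25.8 CPM in control. The bulb score was raised in 3 of the 4 PNO libraries and the striatal score in the other, PNO 2. On the TPM scale the list no longer passed (adjusted p = 0.0818).

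Of the 25 glutamate receptors and transporters, 21 were higher and 4 lower in sign, with a median of 0.17, and the list was higher (adjusted p = 5.44e-04, and adjusted p = 0.407 with an estimated correlation). Adjusted over the list alone 2 members passed, among them Gria1 (adjusted p = 0.00784), against 0 over all genes. The metabotropic receptor gene Grm4 measured 50.8 ± 2.67 CPM in PNO and 34.6 ± 5.21 CPM in control. The other synaptic lists missed the threshold: postsynaptic density (adjusted p = 0.0522) and presynaptic vesicle machinery (adjusted p = 0.104), although Unc13a passed adjusted over its list alone (adjusted p = 0.0155). Among cortical layer markers (adjusted p = 0.640) the upper-layer transcription factor genes Cux1 and Cux2 passed adjusted over the list alone (adjusted p = 0.0341 for each). Cux2 measured 67.1 ± 2.35 CPM in PNO and 47.5 ± 8.71 CPM in control, and Cux1 71.5 ± 4.59 CPM and 56.5 ± 4.84 CPM.

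The 75 nuclear-encoded respiratory chain genes were lower in PNO (adjusted p = 1.50e-12, and adjusted p = 0.476 with an estimated correlation), and 0 members passed adjusted over the list alone or over all genes. Atp5mc3, a subunit of ATP synthase, measured 161 ± 10.8 CPM in PNO and 197 ± 13 CPM in control, and the complex I gene Ndufa9 122 ± 8.14 CPM and 145 ± 5.05 CPM. Of 96 cytosolic ribosomal protein genes 78 were lower and 18 higher in sign, with a median of -0.15, and the list was lower (adjusted p = 2.60e-04, and adjusted p = 0.723 with an estimated correlation). Of the 12 mitochondrially encoded genes 10 were lower in sign, with a median of -0.18, and the list was lower (adjusted p = 0.00136, and adjusted p = 0.407 with an estimated correlation). Mt-atp6 measured 19808 ± 1382 CPM in PNO and 22845 ± 733 CPM in control. In the ribosomal and mitochondrial lists 0 members passed adjusted over the list alone or over all genes. Log2 fold changes in this comparison followed gene length (Spearman's rho 0.44 across 10050 genes, which are not independent replicates), and these transcripts are short, with median lengths of 1307 (respiratory chain) and 1014 (ribosomal) bases against 3114 for all tested genes. With a length trend removed from each library the ribosomal list (adjusted p = 0.384) and the mitochondrial list (adjusted p = 0.602) no longer passed. The ribosomal list also did not pass without the 4 libraries with raised striatal markers (adjusted p = 0.0761).

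The chaperone, interferon response, microglial and astrocyte lists were lower in PNO, and 0 of these 4 passed with an estimated correlation (adjusted p = 0.407 for each). Of 20 genes of the heat shock and unfolded protein response 18 were lower in sign, with a median of -0.19 (adjusted p = 3.22e-06, and adjusted p = 0.407 with an estimated correlation). Hspa5, the chaperone of the endoplasmic reticulum also called BiP, measured 332 ± 28.6 CPM in PNO and 423 ± 43.4 CPM in control. The 16 interferon response genes were lower, 13 of them in sign, with a median of -0.27 (adjusted p = 5.44e-04, and adjusted p = 0.407 with an estimated correlation). The immunoproteasome gene Psmb8 measured 2.45 ± 0.537 CPM and 4.11 ± 0.463 CPM. This list missed the threshold when a mean FPKM of at least 2 was asked for (adjusted p = 0.0561). Of 17 microglial genes 13 were lower in sign, with a median of -0.20 (adjusted p = 0.00136, and adjusted p = 0.407 with an estimated correlation). Tmem119 measured 22.7 ± 2.25 CPM in PNO and 30.3 ± 3.98 CPM in control, and the complement gene C1qa 37.5 ± 5.12 CPM and 56.9 ± 7.23 CPM. Of 16 astrocyte genes 14 were lower in sign, with a median of -0.14 (adjusted p = 0.00441, and adjusted p = 0.407 with an estimated correlation), and Aldh1l1 measured 27.8 ± 6.30 CPM and 37.9 ± 3.09 CPM. In these 4 lists 0 members passed adjusted over the list alone or over all genes. Without control 1 the microglial list (adjusted p = 0.0562) and the astrocyte list (adjusted p = 0.138) no longer passed.

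All 16 circadian clock genes had a positive log2 fold change in PNO, with a median of 0.13 (adjusted p = 0.00760, and adjusted p = 0.407 with an estimated correlation). Ciart, a repressor of the clock, measured 12.8 ± 1.46 CPM in PNO and 7.98 ± 1.08 CPM in control, and it passed adjusted over the list alone (adjusted p = 0.0242) as 1 member against 0 over all genes. The list missed the threshold with the length trend removed (adjusted p = 0.0600). The 9 olfactory bulb genes were higher, 8 of them in sign, with a median of 1.94 (adjusted p = 2.19e-04, and adjusted p = 0.407 with an estimated correlation), and 6 passed adjusted over the list alone against 0 over all genes. Eomes measured 5.16 ± 3.23 CPM in PNO and 0.282 ± 0.134 CPM in control. The 13 striatal genes were all higher in sign, with a median of 0.89 (adjusted p = 0.0426, and adjusted p = 0.723 with an estimated correlation), and 0 passed adjusted over the list alone. That list no longer passed without control 1 (adjusted p = 0.140), control 3 (adjusted p = 0.113) or control 4 (adjusted p = 0.0853) or with limma on log2(FPKM + 0.5) (adjusted p = 0.217), and its sign turned without PNO 2 (adjusted p = 0.180).

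Among single genes, those with small unadjusted p included Srrm2, at 568 ± 39.1 CPM in PNO and 416 ± 19.7 CPM in control, Ddah2, at 2.95 ± 1.42 CPM and 8.63 ± 1.95 CPM, and Tshz1, at 34.0 ± 8.85 CPM and 11.3 ± 1.12 CPM, each with an adjusted p of 0.305. Tshz1 measured 32.7 to 42.0 CPM in the 4 libraries with raised bulb markers, IUO 3 among them, and at most 21.9 CPM in the other 8. It was among the 11 genes of the fit of this comparison alone. The mu opioid receptor gene Oprm1, with 63 counts over the 12 libraries, and the kappa receptor gene Oprk1, with a mean FPKM of 0.403, were below the filter and not tested. The delta receptor gene Oprd1 measured 1.21 ± 0.408 CPM in PNO and 1.03 ± 0.504 CPM in control (adjusted p = 0.821). Penk measured 167 ± 143 CPM and 89.7 ± 36.9 CPM (adjusted p = 0.516), and Pdyn 35.4 ± 29.2 CPM and 26.1 ± 4.17 CPM (adjusted p = 0.754). Both peptide genes were highest in PNO 2, the library with the highest striatal mean. With the striatal and bulb scores as covariates, 1 of the 10 lists called here apart from the striatal and bulb lists kept its call and direction, the mitochondrially encoded genes (adjusted p = 7.32e-07), while 9 of the 10 did without the 4 libraries with raised striatal markers. With the covariates the ribosomal list passed in the other direction, higher in PNO (adjusted p = 1.68e-04), and p values over animals may be too small because each group came from 2 dams.

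The remaining lists did not pass in this comparison. Their adjusted p was 0.0812 for GABA-A receptor subunits, 0.181 for immediate early genes, 0.181 for monoamine receptors, 0.340 for inflammation, 0.383 for myelin and mature oligodendrocytes, 0.383 for the glucocorticoid response and 0.468 for opioid receptors and peptides. It was 0.640 for endothelium and pericytes, 0.757 for oligodendrocyte precursors, 0.802 for meninges, 0.913 for blood, 0.971 for histone genes and 0.982 for choroid plexus and ependyma. In each of these 13 lists 0 members passed over all genes or adjusted over the list alone.

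**Figure D2:**
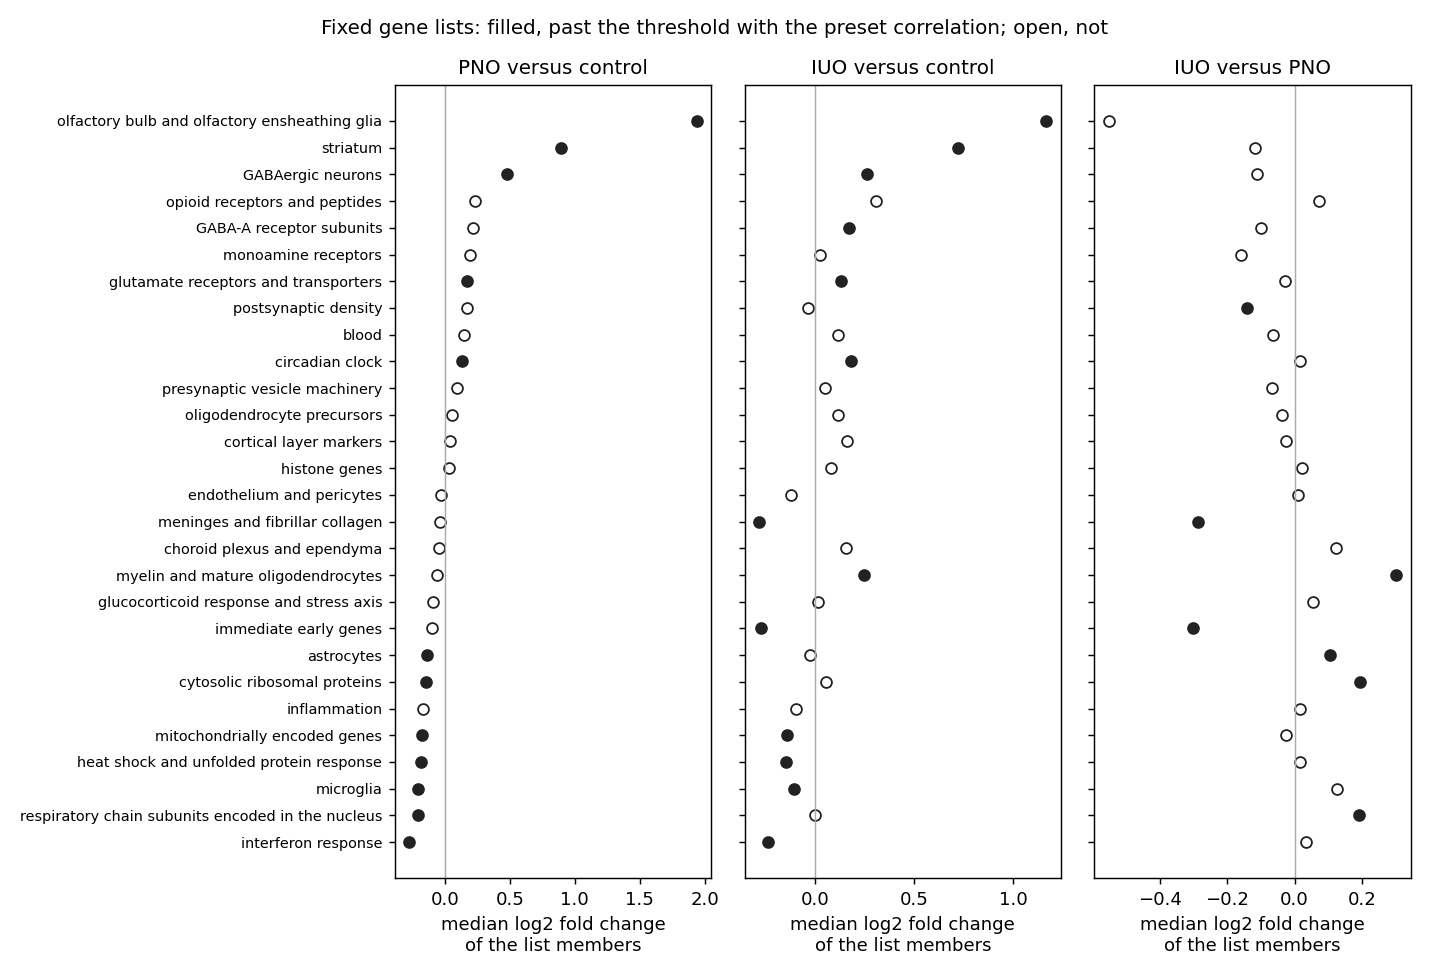
Median log2 fold change over the measured members of each of 28 gene lists in the 3 comparisons, with scales that differ between panels. Filled points mark lists past the threshold with the preset correlation, 12 in PNO against control, 13 in IUO against control and 7 in IUO against PNO, and 0 pass with an estimated correlation.

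The comparison of IUO with control asked what the exposure labelled in utero left in the same tissue, and the labels do not say on which days each group was dosed. The lists of immediate early genes and of the heat shock and unfolded protein response were lower in IUO (adjusted p = 6.62e-09 for each, and adjusted p = 0.248 for each with an estimated correlation). Immediate early genes, which neurons switch on within minutes of firing, had a negative log2 fold change in 19 of 20 members. Nr4a1 measured 75.2 ± 43.5 CPM in IUO and 135 ± 27.9 CPM in control (SD, n = 4 each), and Nptx2, an activity-regulated synaptic pentraxin, 107 ± 7.31 CPM against 164 ± 37.7 CPM, a log2 fold change of -0.62 (SE 0.15). Hspa5 measured 302 ± 51.1 CPM in IUO and 423 ± 43.4 CPM in control, a log2 fold change of -0.49 (SE 0.12), and Gad1 244 ± 40.4 CPM and 182 ± 15.5 CPM. Of all 14170 genes edgeR called 0, with a smallest adjusted p of 0.943. At an unadjusted p under 0.05 it gave 570 genes (327 higher, 243 lower), where chance gives 708. That count rose to 1276 without IUO 4 (smallest adjusted p 0.256), and was 479 to 685 without any other library. Limma with sample weights gave 1323. Pearson's r of log2 CPM between IUO 4 and the other IUO libraries was 0.954 to 0.969, with the lowest r within any group. DESeq2 called 11 genes (9 higher, 2 lower), among them Zwint and Enc1, and limma on log2(FPKM + 0.5) and limma with sample weights called 0 each.

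The median log2 fold change of the 20 immediate early genes was -0.27, and the list was lower (adjusted p = 6.62e-09, and adjusted p = 0.248 with an estimated correlation). Adjusted over the list alone 0 members passed, as over all genes. Dusp6, a phosphatase of the MAP kinase pathway, measured 24.3 ± 5.47 CPM in IUO and 35.8 ± 1.47 CPM in control, and Egr3 32.3 ± 8.51 CPM and 45.0 ± 4.88 CPM. The mean log2 CPM of the list was 4.43 in IUO 1 and 4.22 in IUO 2, against 5.28 in IUO 3, 5.14 in IUO 4 and a mean of 5.20 over the controls. Arc measured 51.5 CPM in IUO 1 and 39.8 CPM in IUO 2, against 306 CPM in IUO 3, 211 CPM in IUO 4 and 304 ± 68 CPM in control. IUO 1 and IUO 2 are the IUO libraries with raised striatal markers, and without the 4 libraries with raised striatal markers the list no longer passed (adjusted p = 0.348). With the striatal and bulb scores as covariates it passed (adjusted p = 4.89e-05).

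The 20 genes of the heat shock and unfolded protein response were lower, 18 of them in sign, with a median of -0.15 (adjusted p = 6.62e-09, and adjusted p = 0.248 with an estimated correlation). Hspa5 passed adjusted over the list alone (adjusted p = 0.0217), as 1 member against 0 over all genes, and it was lower in all 4 IUO libraries than in all 4 control libraries. Pdia6, a disulfide isomerase of the endoplasmic reticulum, measured 136 ± 13.1 CPM in IUO and 161 ± 7.46 CPM in control, and Xbp1 94.4 ± 8.28 CPM and 113 ± 7.52 CPM. The mean log2 CPM of the list was 6.84 in IUO 4 and 6.33, 6.36 and 6.49 in the other IUO libraries, against a mean of 6.63 over the controls. The list no longer passed without the 4 libraries with raised striatal markers (adjusted p = 0.384). All 12 mitochondrially encoded genes were lower in sign, with a median of -0.14 (adjusted p = 5.09e-05, and adjusted p = 0.363 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Mt-co1 measured 39303 ± 2919 CPM in IUO and 46585 ± 3821 CPM in control. The 14 meningeal genes were lower, 12 of them in sign, with a median of -0.28 (adjusted p = 4.71e-06, and adjusted p = 0.363 with an estimated correlation), and 0 passed adjusted over the list alone. Crabp2 measured 5.04 ± 1.01 CPM and 7.73 ± 0.746 CPM.

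Of 14 GABAergic genes 13 were higher in sign in IUO, with a median of 0.26 (adjusted p = 0.00342, and adjusted p = 0.248 with an estimated correlation). The list no longer passed without control 1 (adjusted p = 0.0507), without IUO 3 (adjusted p = 0.214) or on the TPM scale (adjusted p = 0.0755). IUO 3 is the IUO library with raised bulb markers, and without all 4 such libraries the adjusted p was 0.355. Of 25 glutamate receptors and transporters 19 were higher in sign, with a median of 0.13 (adjusted p = 0.0118, and adjusted p = 0.434 with an estimated correlation). Gria4 measured 48.9 ± 3.87 CPM in IUO and 40.0 ± 4.27 CPM in control. That list no longer passed without control 2 (adjusted p = 0.0842), IUO 1 (adjusted p = 0.106) or IUO 2 (adjusted p = 0.259), or on the TPM scale (adjusted p = 0.0592), and its sign turned without the 4 libraries with raised striatal markers (adjusted p = 0.524). Of 11 GABA-A receptor subunits 9 were higher in sign, with a median of 0.17 (adjusted p = 0.0213, and adjusted p = 0.446 with an estimated correlation). That list no longer passed with limma on log2(FPKM + 0.5) (adjusted p = 0.0791), nor without control 1 (adjusted p = 0.0738), control 4 (adjusted p = 0.0724), IUO 1 (adjusted p = 0.140) or IUO 2 (adjusted p = 0.309), and its sign turned without the 4 striatal-marker libraries (adjusted p = 0.634). In these 3 lists 0 members passed adjusted over the list alone or over all genes.

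Of 16 circadian clock genes 12 were higher in sign in IUO, with a median of 0.18 (adjusted p = 0.00467, and adjusted p = 0.248 with an estimated correlation). Dbp, an output gene of the clock, measured 192 ± 8.81 CPM in IUO and 150 ± 17.9 CPM in control. The list no longer passed without IUO 3 (adjusted p = 0.0601), without the 4 libraries with raised striatal markers (adjusted p = 0.265) or without the 4 with raised bulb markers (adjusted p = 0.0934). Of 19 myelin genes 18 were higher in sign, with a median of 0.25 (adjusted p = 0.00845, and adjusted p = 0.664 with an estimated correlation), and Enpp2 measured 98.7 ± 40.4 CPM in IUO and 78.3 ± 16.0 CPM in control. The mean log2 CPM of this list was 7.69 in IUO 1 and 8.03 in IUO 2, against 6.80 in IUO 3 and 7.13 in IUO 4. It no longer passed without control 3 (adjusted p = 0.326), control 4 (adjusted p = 0.0724) or IUO 1 (adjusted p = 0.20), with limma on log2(FPKM + 0.5) (adjusted p = 0.0791) or with the Y-linked covariate (adjusted p = 0.0657). The sign turned without IUO 2 (adjusted p = 0.744), and without the 4 libraries with raised striatal markers the list passed as lower (adjusted p = 0.0109). In both lists 0 members passed adjusted over the list alone or over all genes.

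Of 16 interferon response genes 13 were lower in sign in IUO, with a median of -0.24 (adjusted p = 0.00845, and adjusted p = 0.504 with an estimated correlation), and Bst2 measured 5.58 ± 1.88 CPM in IUO and 8.22 ± 3.59 CPM in control. The list no longer passed without control 2 (adjusted p = 0.0527), control 4 (adjusted p = 0.355) or the 4 libraries with raised striatal markers (adjusted p = 0.619). Of 17 microglial genes 14 were lower in sign, with a median of -0.10 (adjusted p = 0.0440, and adjusted p = 0.531 with an estimated correlation). Trem2, a microglial receptor gene, had the opposite sign at 10.3 ± 3.15 CPM in IUO and 6.99 ± 0.610 CPM in control. That list no longer passed with the length trend removed (adjusted p = 0.0556), in a fit of the 2 groups alone (adjusted p = 0.0510), without the 4 striatal-marker libraries (adjusted p = 0.678), without the 4 bulb-marker libraries (adjusted p = 0.175), or without control 1 (adjusted p = 0.576), control 4 (adjusted p = 0.0589), IUO 1 (adjusted p = 0.0631), IUO 2 (adjusted p = 0.464) or IUO 3 (adjusted p = 0.147). The 13 striatal genes were all higher in sign, with a median of 0.72 (adjusted p = 0.00467, and adjusted p = 0.636 with an estimated correlation). They no longer passed without IUO 2 (adjusted p = 0.744) or with limma on log2(FPKM + 0.5) (adjusted p = 0.0577). The 9 bulb genes were all higher in sign, with a median of 1.17 (adjusted p = 0.00467, and adjusted p = 0.504 with an estimated correlation). They no longer passed with limma on log2(FPKM + 0.5) (adjusted p = 0.0791) or with sample weights (adjusted p = 0.139), and the sign turned without IUO 3 (adjusted p = 0.778). In these 4 lists 0 members passed adjusted over the list alone or over all genes.

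Zwint, which encodes a kinetochore protein (ENSRNOG00000048682, chromosome 20, 15938157 to 15953957), measured 1560 ± 480 CPM in IUO and 2729 ± 200 CPM in control, a log2 fold change of -0.81 (SE 0.16). It did not pass over all genes (adjusted p = 0.943), and it passed without IUO 2 (adjusted p = 4.91e-04), which stood at 2279 CPM where the other 3 IUO libraries stood at 1301 to 1351 CPM. Enc1, an actin-binding protein gene of neurons, measured 612 ± 6.97 CPM in IUO and 752 ± 9.22 CPM in control (adjusted p = 0.998). The list of opioid receptors and peptides did not pass (adjusted p = 0.0637), and 0 of its 7 members passed adjusted over the list alone. Oprd1 measured 1.67 ± 0.328 CPM in IUO and 1.03 ± 0.504 CPM in control, Penk 162 ± 90.1 CPM and 89.7 ± 36.9 CPM, and Pdyn 33.4 ± 23.8 CPM and 26.1 ± 4.17 CPM, each with an adjusted p of 0.998. With the striatal and bulb scores as covariates, 2 of the 11 lists called here apart from the striatal and bulb lists kept their call and direction, the immediate early genes and the mitochondrially encoded genes (adjusted p = 6.29e-06).

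Outside these lists, Nptx2 passed adjusted over the postsynaptic density list alone (adjusted p = 0.0319), S100a9 over the blood list alone (adjusted p = 0.0228) and Kcne2 over the choroid plexus list alone (adjusted p = 0.0360), each as 1 member against 0 over all genes. The lists themselves did not pass, with an adjusted p of 0.277 for postsynaptic density, 0.613 for blood and 0.280 for choroid plexus and ependyma. The other lists that did not pass had an adjusted p of 0.0983 for the respiratory chain, 0.102 for inflammation, 0.185 for endothelium and pericytes, 0.296 for histone genes, 0.328 for cortical layer markers and 0.328 for the glucocorticoid response. It was 0.568 for presynaptic vesicle machinery, 0.800 for monoamine receptors, 0.836 for ribosomal proteins, 0.944 for astrocytes and 0.981 for oligodendrocyte precursors, and 0 members of these 11 lists passed adjusted over the list alone.

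**Figure D3:**
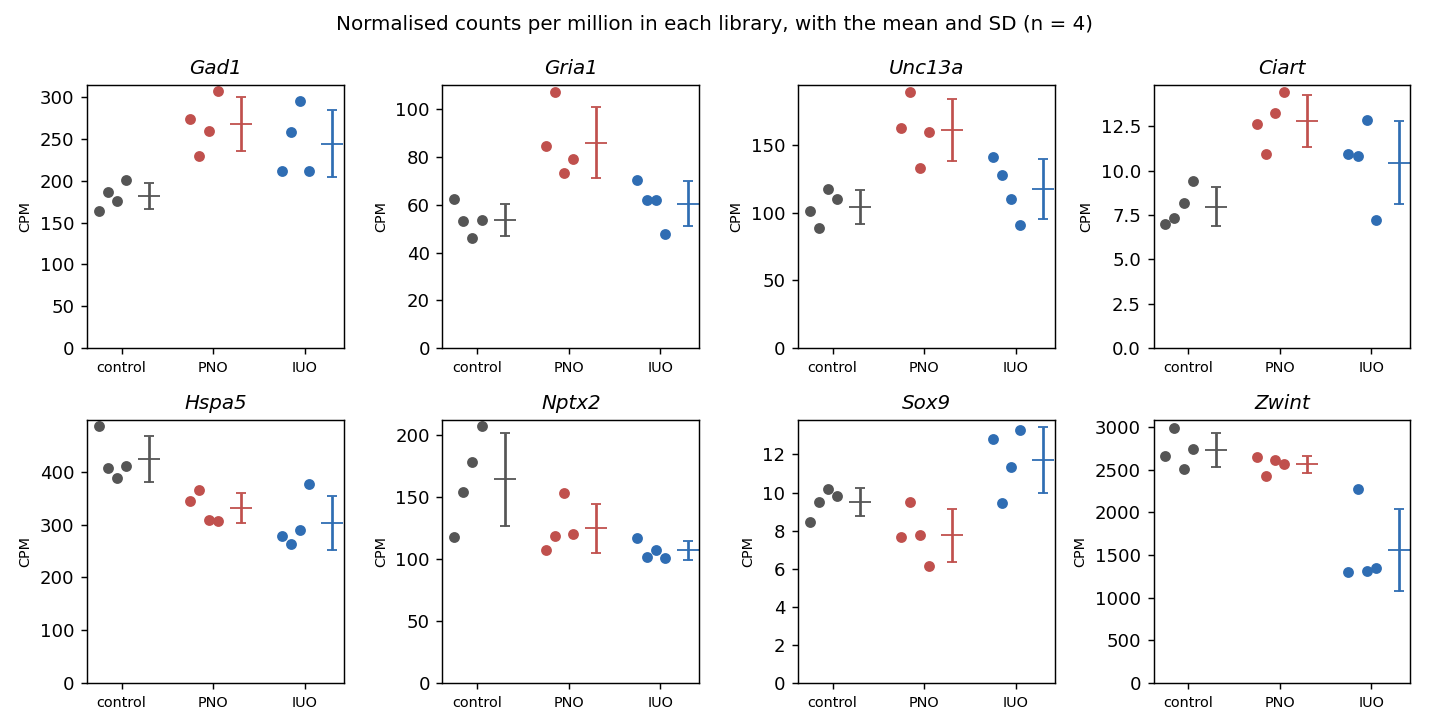
CPM of Gad1, Gria1, Unc13a, Ciart, Hspa5, Nptx2, Sox9 and Zwint in each library, with the mean and SD of each group (n = 4). Gad1 is higher in all 4 PNO libraries than in all 4 control libraries, and IUO 2 stands apart from the other 3 IUO libraries for Zwint (2279 CPM).

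The comparison of IUO with PNO tested whether the effects of the 2 labelled exposures differed. The respiratory chain, ribosomal protein, myelin and astrocyte lists were higher in IUO than in PNO, and the meningeal, postsynaptic density and immediate early lists were lower. These are 7 of 28 lists, and 0 of the 7 passed with an estimated correlation (adjusted p = 0.940 for each). Atp5mc3 measured 192 ± 7.46 CPM in IUO and 161 ± 10.8 CPM in PNO (SD, n = 4 each), a log2 fold change of 0.25 (SE 0.07), beside 197 ± 13 CPM in control. Sox9, a transcription factor of astrocytes, measured 11.7 ± 1.74 CPM in IUO and 7.75 ± 1.38 CPM in PNO, a log2 fold change of 0.60 (SE 0.15). No gene passed over all 14170: edgeR called 0, with a smallest adjusted p of 0.714 and 953 genes (520 higher, 433 lower) at an unadjusted p under 0.05 where chance gives 708, DESeq2 called 8 (3 higher, 5 lower), among them Zwint, Retsat and Ddah2, and limma on log2(FPKM + 0.5) and limma with sample weights called 0 each.

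Of the 75 respiratory chain genes 69 were higher in sign in IUO, with a median of 0.19 (adjusted p = 4.48e-10, and adjusted p = 0.940 with an estimated correlation). The mean log2 CPM of the respiratory chain list was 6.57 in IUO 4 and 6.05, 5.94 and 6.21 in the other IUO libraries, against a mean of 6.05 over the PNO libraries, and without IUO 4 the adjusted p was 0.0454. Of the 96 ribosomal protein genes 82 were higher in sign, with a median of 0.20 (adjusted p = 1.87e-04, and adjusted p = 0.940 with an estimated correlation). The mean log2 CPM of the ribosomal list was 6.15 in IUO 4 and 5.25, 5.25 and 5.63 in the other IUO libraries, and the sign of the test turned without IUO 4 (adjusted p = 0.0689) and with sample weights (adjusted p = 0.221). With the length trend removed the ribosomal list no longer passed (adjusted p = 0.350). Log2 fold changes followed gene length here too, in the other direction (Spearman's rho -0.37 across the same genes). Within single libraries, rho of gene length with the deviation from the gene mean was lowest of all in IUO 4 (-0.407). In both lists 0 members passed adjusted over the list alone or over all genes. All 19 myelin genes were higher in sign, with a median of 0.30 (adjusted p = 0.00137, and adjusted p = 0.940 with an estimated correlation), and 0 passed adjusted over the list alone. Aspa, an oligodendrocyte enzyme gene, measured 20.5 ± 2.52 CPM in IUO and 16.6 ± 4.13 CPM in PNO. The myelin list no longer passed without IUO 1 (adjusted p = 0.113) or IUO 2 (adjusted p = 0.549), and its sign turned without the 4 libraries with raised striatal markers (adjusted p = 0.658). Of 16 astrocyte genes 14 were higher in sign, with a median of 0.11 (adjusted p = 0.00234, and adjusted p = 0.940 with an estimated correlation), and Sox9 passed adjusted over the list alone (adjusted p = 0.0298), as 1 member against 0 over all genes. Gfap measured 398 ± 34.2 CPM in IUO and 311 ± 58.6 CPM in PNO.

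All 14 meningeal genes were lower in sign in IUO than in PNO, with a median of -0.29 (adjusted p = 0.00127, and adjusted p = 0.940 with an estimated correlation). Col1a1 measured 56.5 ± 14.0 CPM in IUO and 113 ± 70.4 CPM in PNO, where PNO 4 stood at 211 CPM. The list no longer passed without PNO 3 (adjusted p = 0.0956) or IUO 2 (adjusted p = 0.0723). Of 25 postsynaptic density genes 20 were lower in sign, with a median of -0.14 (adjusted p = 0.00142, and adjusted p = 0.940 with an estimated correlation). Dlgap2, a scaffold gene, measured 21.1 ± 1.85 CPM in IUO and 25.1 ± 1.76 CPM in PNO. That list no longer passed without IUO 4 (adjusted p = 0.0689) or with sample weights (adjusted p = 0.0760). Of 20 immediate early genes 14 were lower in sign, with a median of -0.30 (adjusted p = 0.00185, and adjusted p = 0.940 with an estimated correlation), and Jun measured 67.7 ± 3.73 CPM and 79.2 ± 6.11 CPM. It no longer passed without PNO 4 (adjusted p = 0.0750), IUO 1 (adjusted p = 0.126) or IUO 2 (adjusted p = 0.324), and its sign turned without the 4 libraries with raised striatal markers (adjusted p = 0.658). In these 3 lists 0 members passed adjusted over the list alone or over all genes. With the striatal and bulb scores as covariates, 6 of the 7 lists called here kept their call and direction, all but the ribosomal list (adjusted p = 0.415).

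Among single genes of this comparison, Zwint had a log2 fold change of -0.72 (SE 0.16, adjusted p = 0.714) and passed without IUO 2 (adjusted p = 0.00131). Retsat, a retinol saturase gene, measured 111 ± 14.0 CPM in IUO and 55.9 ± 23.9 CPM in PNO (adjusted p = 0.714), and it passed without PNO 3 (adjusted p = 0.00291). The cytochrome c gene Cycs measured 281 ± 35.7 CPM and 216 ± 13.2 CPM (adjusted p = 0.714). The opioid list did not pass (adjusted p = 0.701), while 2 of its 7 members passed adjusted over the list alone against 0 over all genes (adjusted p = 0.0410 for each). Pomc, a precursor of beta-endorphin, measured 1.45 ± 0.393 CPM in IUO and 5.41 ± 4.82 CPM in PNO, where PNO 2 stood at 11.5 CPM and PNO 3 at 7.08 CPM. Pnoc, the nociceptin precursor gene, measured 11 ± 2.63 CPM and 7.88 ± 0.545 CPM. Oprd1 (adjusted p = 0.739), Pdyn (adjusted p = 0.975) and Penk (adjusted p = 0.990) did not pass. The cytokine signalling inhibitor gene Socs3 passed adjusted over the inflammation list alone (adjusted p = 0.0408), at 1.53 ± 0.217 CPM in IUO and 2.71 ± 0.944 CPM in PNO, while that list did not pass (adjusted p = 0.917).

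The other lists did not pass in IUO against PNO. The adjusted p was 0.118 each for monoamine receptors, olfactory bulb and microglia, 0.139 for glutamate receptors and transporters, 0.170 for interferon response, 0.276 for presynaptic vesicle machinery, 0.639 each for histone genes and choroid plexus, 0.669 for GABAergic neurons and 0.702 for blood. It was 0.782 each for endothelium and pericytes and the circadian clock, 0.787 for the heat shock and unfolded protein response, 0.795 for oligodendrocyte precursors, 0.917 each for the glucocorticoid response, cortical layer markers and mitochondrially encoded genes, 0.969 for GABA-A receptor subunits and 0.972 for the striatum, and 0 members of these 19 lists passed adjusted over the list alone. Among lists that did not pass, the sign of the test and that of the median differed for 1 list in PNO against control, 4 in IUO against control and 6 in IUO against PNO.

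The PNO and IUO effects were set against each other across genes. Pearson's r of the log2 fold changes was 0.589 over 14170 genes, which are not independent replicates and share the same 4 control libraries. On differences of mean log2 CPM r was 0.539, and 45 of 100 simulations of unchanged groups with shared controls gave an r at least as large, with a mean of 0.461. When the controls were split into 2 and 2, so that no control library was shared, r averaged 0.149 over 6 splits (0.0698 to 0.210). Each difference there rests on 2 controls and not 4, and the added noise also lowers r. The covariance was 0.0488 as observed, 0.0353 on average in the simulations and 0.0179 on average over the splits (0.00908 to 0.0243). At an unadjusted p under 0.05, 154 genes were higher and 78 lower in both comparisons, where 22.3 and 10.3 would overlap if the comparisons were independent, which shared controls do not allow.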

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

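The tests of an exposure effect on the bulb list, of neighbouring regions and of gene length were chosen only after the results they bear on had been seen, while the second bulb list and the splits of the samples were set before their results were seen.

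Olfactory bulb markers were raised in 4 exposed libraries, PNO 1, PNO 3, PNO 4 and IUO 3, and in 0 of the 4 controls. An exposure effect present in every exposed animal is argued against by 3 exposed libraries with a mean of the bulb list at or below that of the highest control library. A candidate source is olfactory bulb tissue in those dissections: of 11 measured genes of a second bulb list, 8 were higher in each of the 4 libraries than in each of the other 8, where chance gives 0.0222 of the 11, and 172 of all 14170 tested genes did so. All 11 had counts in at least 1 control library, and Meis2, at 163 to 169 CPM in the 4 libraries against 78.8 to 129.8 CPM, had been seen before: 7 of the 10 genes without it separated the libraries, among them Shisa8, at 29.8 to 38.7 CPM against 3.87 to 7.72 CPM, and Scgn, at 12.97 to 19.02 CPM against 2.20 to 3.94 CPM. An exposure effect in some animals only, and differences between dams, stay open, because the labels do not tie animals to dams.

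The GABAergic list was higher in PNO than in control (adjusted p = 0.00249, and adjusted p = 0.407 with an estimated correlation). As the whole cause a gene length trend is argued against, since with the trend removed the list passed (adjusted p = 6.14e-04), and so is striatal RNA, since it passed without the 4 libraries with raised striatal markers (adjusted p = 4.27e-04). RNA of neighbouring regions may account for it: with striatal and bulb scores as covariates the adjusted p was 0.858, and the mean log2 fold change over the 14 members went from 0.43 (SD over members 0.59) to 0.01 (SD 0.21) while the median SE was 0.23 and 0.22, so the call ended because the differences shrank. The bulb score was raised in 3 of the 4 PNO and 0 of the 4 control libraries, so the covariates also remove part of any exposure effect that goes with them, and such an effect stays open.

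The respiratory chain list was lower in PNO than in control (adjusted p = 1.50e-12, and adjusted p = 0.476 with an estimated correlation). Without the 4 libraries with raised striatal markers the list passed with the preset correlation (adjusted p = 1.54e-08). Its means (log2 CPM) were then 6.07, 6.25 and 5.94 in PNO 1, PNO 3 and PNO 4. They were 6.15, 6.23 and 6.26 in control 1, control 3 and control 4. These means overlap and the members vary together, so striatal RNA as the whole cause stays open. With the gene length trend removed the list also passed with the preset correlation (adjusted p = 4.94e-06). Of 10000 random lists matched on length and expression 0 had a median as low as -0.20. Their own median was -0.14, with a central range of -0.17 to -0.10. Random lists do not carry the correlation among the members of this list, estimated at 0.587. The list mean also went with the length trend of each library, taken as Spearman's rho of gene length with the deviation from the gene mean. In PNO 1, PNO 2 and PNO 4 rho was 0.356, 0.426 and 0.272, with list means (log2 CPM) of 6.07, 5.95 and 5.94. In PNO 3 rho was -0.0944 and the list mean 6.25, and in the controls rho ran from -0.357 to 0.0463. In IUO 4 rho was -0.407 and the list mean 6.57. These values therefore do not settle whether a length trend was the whole cause. With striatal and bulb scores as covariates the adjusted p was 0.788 and the mean log2 fold change went from -0.12 (SD over members 0.78) to 0.14 (SD 0.80), and the median from -0.20 to 0.03, so the call ended because the difference shrank and turned. In 2 of the 4 libraries with raised bulb markers, PNO 3 (6.25) and IUO 3 (6.21), the list mean (log2 CPM) lay within that of the controls (6.15 to 6.26). RNA of the striatum, RNA of both regions together and an exposure effect that goes with the scores stay open.

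Other splits of the 8 libraries of each comparison, 35 in all with the real one, were fitted in the same way. For genes at an unadjusted p under 0.05 chance could not be excluded: 2 splits gave as many as PNO against control (1564, highest other 1635), 19 as many as IUO against control (570, highest other 2277) and 10 as many as IUO against PNO (953, highest other 2884). The same holds for the lists, where 11, 12 and 25 splits gave as many as the 12, 13 and 7 called, with 17, 19 and 16 the highest others. For the 117 genes of DESeq2 in PNO against control 1 split of 35, the real one, gave as many, the smallest share these splits can give, and the highest other gave 79. Each of the other counts set against the splits was matched by another split, and animals of a dam cannot be exchanged freely. Chance is therefore argued against only for this count taken alone and only as far as the 8 animals can be exchanged. Differences between dams stay open, because animals of a dam fall on the same side of the real split, and that split also parts the 3 libraries with raised bulb markers in this comparison from the controls. In IUO against PNO a split of PNO 1, PNO 2, IUO 1 and IUO 2 from the rest called 105 genes with edgeR where the real split called 0, and the split of the 4 libraries with raised bulb markers from the other 4 called 62, which points to a structure of the samples other than the groups. The split with 105 genes and the DESeq2 split with 79 both part the libraries numbered 1 and 2 from those numbered 3 and 4. The first also keeps the striatal-marker libraries PNO 2, IUO 1 and IUO 2 together, and the second control 2 and PNO 2. Number and striatal markers can therefore not be told apart in these splits. In IUO against control the same parting by number, which keeps control 2, IUO 1 and IUO 2 together, gave 1782 genes at an unadjusted p under 0.05. Control 1, control 2, IUO 3 and IUO 4 against the rest, which parts control 2 from IUO 1 and IUO 2, gave 2044. The highest count, 2277, came from control 1, control 3, IUO 1 and IUO 2 against the rest. All splits that part IUO 1 and IUO 2 from IUO 3 and IUO 4 gave 1055 to 2277, whichever controls went with them. Splits that do not part them so reached up to 1985.

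In groups of 4, a library far from the other 3 was found in 36 of 501 groups of values tested, where chance flags about 1 in 20, or 25. PNO 2 accounted for 14 of the 36. Among list means (log2 CPM), PNO 2 stood apart for myelin (7.65), microglia (4.13), GABAergic neurons (5.82), striatum (6.34) and olfactory bulb (2.48), control 2 for striatum (4.68) and IUO 3 for the sex-linked list (4.28). Among single genes (log2 CPM), PNO 2 stood apart for Eomes (-0.99), Tbx21 (-0.33), Cdhr1 (4.41), Rpl17 (6.40), Psmb9 (-0.18), Penk (8.58), Pdyn (6.31), Th (1.00) and Dcn (3.41). PNO 1 stood apart for Dnaja1 (7.75), Enc1 (9.52) and Xbp1 (6.51), PNO 3 for Grm4 (5.78), Atp5mg (6.99) and Fmod (4.66), and PNO 4 for Rps27l (1.51). IUO 4 stood apart for Dnaja1 (7.85), Wdr41 (5.57), Trem2 (3.91), Aldh1a2 (4.46) and Fmod (4.13), and IUO 2 for Zwint (11.15) and Pcsk1 (3.93). Control 2 stood apart for Drd2 (4.00), Mt-nd1 (13.50) and Rpl38 (1.65), control 3 for Gabrb2 (2.15) and S100b (9.76), and control 4 for Trim45 (3.53).

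The test of IUO against PNO called 7 lists with the preset correlation. Of 35 splits of these 8 libraries, the real one among them, 25 called at least as many, so chance is not excluded for this count. The adjusted p was 4.48e-10 for the respiratory chain, 1.87e-04 for ribosomal proteins, 0.00127 for meninges, 0.00137 for myelin, 0.00142 for postsynaptic density, 0.00185 for immediate early genes and 0.00234 for astrocytes. With an estimated correlation the adjusted p of each was 0.940.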

How the results depend on the processing

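The alternatives with DESeq2, covariates, left-out marker libraries and the gene length trend were chosen after the data were seen. Limma on log2(FPKM + 0.5) was the planned main test and became an alternative after the data were seen, and the rest were planned. The planned Xist covariate was not run, since the table holds no Xist. The cause of each difference given here was not tested. Of 4645 values of named genes under alternatives 4476 kept their direction and side of the threshold, 64 passed only under the alternative and 105 of uncalled genes changed sign. These sign changes were counted as moves, a choice made after they were seen.

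Genes called in PNO against control (0 with edgeR) numbered 117 with DESeq2, 9 with DESeq2 and striatal and bulb covariates, 32 with sample weights, 11 in a fit of 2 groups, 3 without the 4 bulb-marker libraries, and 1 each with limma on log2(FPKM + 0.1), log2(FPKM + 0.5), log2(FPKM + 1) and the TPM scale and with the covariates without or with the Y-linked level. In IUO against control (0) they numbered 11 with DESeq2, 42 with DESeq2 and covariates, 4 without the striatal-marker and 1 without the bulb-marker libraries. In IUO against PNO (0) they numbered 8 with DESeq2, 8 with DESeq2 and covariates, 3 without the striatal-marker and 3 without the bulb-marker libraries. Leaving out each library gave 0 to 1 gene in every comparison, with 1 gene without control 2 in each comparison with control, Zwint without IUO 2 and Retsat without PNO 3.

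Lists called (12, 13 and 7) numbered 0 in each comparison with an estimated correlation. With covariates they numbered 4 in PNO and 5 in IUO against control, with the Y-linked level added 7 and 6, and on the TPM scale 7 in IUO against control. Leaving out each library gave 10 to 15, 9 to 17 and 6 to 9 lists. The correlation of the PNO and IUO effects (0.589) was 0.217 without the bulb-marker libraries, 0.804 with striatal and bulb covariates and 0.394 to 0.657 leaving out each library. Without the bulb-marker libraries PNO 2 is the only PNO library and is assumed to vary like the other groups, so values of that setting that involve PNO are not read as evidence on bulb RNA. With the replicate number as a block edgeR called 0 genes in each comparison and 14, 13 and 9 lists, with a correlation of 0.567, and of the called lists only microglia in IUO against control was lost (adjusted p = 0.0527). Genes at an unadjusted p under 0.05 with the block numbered 1780, 705 and 1144, against 1564, 570 and 953 without it. Deviations from the group means of libraries that share a number correlated at 0.0540 to 0.120, 0.0153 to 0.142 and 0.0579 to 0.411 in the 3 comparisons, so all 12 were positive, but not all were over 0.1, and control 1 correlated better with PNO 2 (0.110) than with PNO 1 (0.0622). Libraries with different numbers correlated at -0.153 to 0.152, -0.170 to 0.0767 and -0.302 to 0.203. These ranges overlap with those of shared numbers, but an overlap of ranges does not test for pairing. The labels do not say what the numbers mark, so they were not taken to pair animals in the main test. The 12 positive values and the higher counts with the block go with something shared by number. Whether the numbers mark such a thing stays open.

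The sign of a called list turned, with these adjusted p. With striatal and bulb covariates it did so in PNO against control for microglia (0.858), ribosomal proteins (1.68e-04) and the respiratory chain (0.788), and in IUO against control for microglia (0.586). With the Y-linked level added it did so in PNO for astrocytes (0.905), microglia (0.905), ribosomal proteins (7.64e-05) and the respiratory chain (0.705), and in IUO for myelin (0.499) and microglia (0.470). Without the striatal-marker libraries it did so in IUO against control for myelin (0.0109), GABA-A receptors (0.634), glutamate receptors (0.524) and striatum (0.698), and in IUO against PNO for immediate early genes (0.658) and myelin (0.658). Without the bulb-marker libraries it did so for the bulb list in PNO (0.283) and IUO (0.705) and for meninges in IUO against PNO (0.207). With sample weights it did so for ribosomal proteins in IUO against PNO (0.221). Leaving out 1 library turned the striatal list in PNO without PNO 2 (0.180, range over left-out libraries 0.00123 to 0.180), myelin in IUO without IUO 2 (5.29e-08 to 0.744), bulb in IUO without IUO 3 (1.83e-05 to 0.778), and ribosomal proteins in IUO against PNO without IUO 4 (0.0689, range 4.83e-12 to 0.0689). The striatal and bulb lists were not read under covariates built from them, and leaving out the libraries chosen by their scores fixes the loss of their calls. Median-of-ratios size factors, no filter and robust estimation kept the side of the threshold of every gene count. Oprm1 (63 counts over 12 libraries) stood below the filter of the main test.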

Other observations

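The DESeq2 test and the counts of genes that follow the marker libraries were chosen only after the data were seen. Several genes with the smallest unadjusted p in a comparison belong to no list, and edgeR called none of those given here (adjusted p of 0.305, 0.998 and 0.714 in the 3 comparisons), while DESeq2 called Chd8, Tiam1, Sipa1l1, Ncoa3, Ndufaf4 and Ass1. In PNO against control the chromatin remodeller gene Chd8 measured 71.8 ± 3.17 CPM in PNO and 55.8 ± 2.26 CPM in control (SD, n = 4 each). The Rac activator gene Tiam1 measured 58.5 ± 5.0 CPM and 38.6 ± 4.11 CPM, the spine protein gene Sipa1l1 170 ± 11.9 CPM and 115 ± 12.9 CPM, and the coactivator gene Ncoa3 13.9 ± 1.48 CPM and 8.01 ± 0.902 CPM. In IUO against control the complex I assembly gene Ndufaf4 measured 18.5 ± 3.59 CPM in IUO and 9.29 ± 1.63 CPM in control, Wdr41 41.8 ± 3.89 CPM and 29.1 ± 3.76 CPM, and the prohormone convertase gene Pcsk1 17.5 ± 1.56 CPM and 23.4 ± 1.15 CPM. In IUO against PNO the arginine synthesis gene Ass1 measured 9.54 ± 0.651 CPM in IUO and 13.4 ± 1.04 CPM in PNO, the growth factor gene Bmp6 17.1 ± 2.06 CPM and 26.0 ± 5.07 CPM, and the lysosomal gene Sgsh 2.80 ± 0.366 CPM and 5.69 ± 1.64 CPM.

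Of the 117 genes DESeq2 called in PNO against control, 103 had PNO and control libraries that did not overlap, as did 1394 of all 14170 genes, where chance gives 2.86% of genes. The 117 were picked by their difference between these same libraries, so few of them could overlap and the chance share is no measure for them. Of the 117, 20 were among the 172 genes higher in each of the 4 libraries with raised bulb markers than in each of the other 8. Those 4 libraries are PNO 1, PNO 3, PNO 4 and IUO 3, with no control, so the selection favours this overlap too.

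Oprm1 counts summed to 6 in control, 32 in PNO and 25 in IUO libraries, and Oprk1 counts to 403, 558 and 448. Oprm1 had 0 to 14 counts per library and stood below the filter.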
